A study of Mus musculus with 4 samples.

How the data were processed

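Total RNA from quadriceps muscle was isolated with a silica-column kit, and between 15 and 40 ng of it was amplified and labelled with biotin by the manufacturer's 2-cycle procedure, per the labels' protocols. The cRNA was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, which carry 1 colour, per the series' design text. The amplification starts from the 3' end of transcripts and repeating it can shorten the cRNA.

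The deposited table held 1 log2 value for each probe set and array, made by the authors. Its values ran from 4.90 to 13.7, as log2 summaries of such arrays do, but the log base, the summary and normalization method, the software and any filter are not given in the sources used here. The arrays' medians differed by at most 0.037, so the values had been brought to a common level before deposit. Probe sets were named by mouse UniGene cluster (17753 by number alone and 114 with a strand sign) and not by the manufacturer's identifiers, so probes had been regrouped by cluster. No table used here pairs cluster numbers with genes, and names were not inferred. The 64 control rows stayed out of the comparisons of the groups. Rows named for the same spike transcript differed in level, as the closing section describes, so their names were in doubt and no RNA quality ratio was computed from them. Scanner files were not used here. The precision of the values is limited by the number of arrays, 4, and no signal over background was known.

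The samples were grouped by their titles into MuRF1 transgenic (n = 2) and wild type (n = 2). The series' text speaks of 2 pairs, but no label says that equal replicate numbers mark a pair, so the number was left out of the reported fit and used as a block in an alternative. The values were kept as deposited. Probe sets with a mean over the 4 arrays below the 40th percentile, a log2 value of 6.02, were left out, which removed 7147 and kept 10720. Transgenic and wild-type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, 2 residual degrees of freedom and 4.38 prior degrees of freedom), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. A permutation test of 2 against 2 arrays cannot give a two-sided p below 0.33. A second measure, which needs no estimate of the spread, counted probe sets at least 2-fold apart in each of the 4 cross comparisons of arrays. The comparison of the groups was set before the data were examined, as were its alternatives except array weights, the replicate block with cyclic loess and a filter on first-component loading.

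The preset rule named probe sets past the threshold and filled free places with those that had an unadjusted p under 0.01, an absolute log2 difference of at least 1 and no overlap between groups. With no gene names, at most 2 probe sets in each direction are named, and 1 met the rule. The rule's other parts, namely Trim63, 32 lists of pathway genes and cell type markers and a few single genes, needed gene names, so 0 lists were tested.

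The test was tested on simulated data with the real means and with variances drawn from the fitted prior. In 10 runs, 200 of 10720 probe sets were changed by 1.5-fold, 2-fold or 4-fold. The test recovered 98.6% of 4-fold, 81.3% of 2-fold and 39.0% of 1.5-fold changes, with 6.9 false calls per run. It made 0.10 calls per run where nothing was changed. The simulated noise was independent between probe sets and arrays, whereas the groups' replicate differences in the real arrays correlated across probe sets (r = 0.48). The changed probe sets also ease the adjusted threshold, so these shares do not give the power of the real comparison. The same changes were also added to the real arrays. Alternatives were other variance models, a test without moderated variances, other filters, other normalizations, the replicate number as a block, other thresholds and leaving out each array in turn.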

Results

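Gene expression was measured in quadriceps muscle of 12-week-old male mice of the FVBN strain. The study compared mice that overexpress MuRF1 with wild-type mice. MuRF1, encoded by Trim63, is a muscle-specific E3 ubiquitin ligase best known for its part in muscle protein breakdown, and the study's title names its subject as the regulation of systemic carbohydrate metabolism by MuRF1. The MuRF1 transgenic group held 2 arrays and the wild-type group held 2 arrays, each hybridised with labelled cRNA of 1 sample. The sample labels name no individual animals, although the series' text speaks of 2 transgenic and wild-type pairs, so the tests measure the spread between these samples. The deposited table listed 17867 probe sets and 64 control rows for every array. The median log2 expression of the arrays lay between 6.18 and 6.22.

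The comparison of transgenic with wild-type muscle asked which transcripts change when MuRF1 is overexpressed. None of the 10720 probe sets tested changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and the smallest adjusted p was 0.81. An unadjusted p under 0.05 (limma) was reached by 315 probe sets, 2.94% of those tested, of which 215 were lower and 100 higher in transgenic muscle. Chance gives a proportion of 0.05 where nothing changes, so these are fewer than chance gives. A test of each probe set on its own spread, without limma's moderation, called 0 probe sets after adjustment and 380 before it. These 380 were 3.54% of those tested, also below that proportion, with 167 lower and 213 higher. The excess of lower values therefore depended on the test. It was not seen without transgenic replicate 1, but that fit also takes its spread from the wild-type arrays alone. Whether the array or the changed spread was the reason was not tested. The series' text does not say that the replicate numbers mark the pairs. With the replicate number as a block, 18 probe sets passed adjusted p under 0.05 (limma), 16 lower and 2 higher in transgenic muscle. With cyclic loess added to the block 1 passed. The block fit had 1 residual and 9.09 prior degrees of freedom, so its calls lean mostly on a variance shared over probe sets. Whether any probe set passed without 1 array depended on the array left out. Such a fit leaves a lone array in a group, which is assumed to vary like the other group. Without wild-type replicate 1, the prior degrees of freedom were 52.0, against 4.38 with all 4 arrays and no block. Calls from that fit therefore also lean on a variance shared over probe sets.

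No probe set was at least 2-fold apart, in one direction, in all 4 comparisons of a transgenic with a wild-type array. At 1.5-fold, 4 probe sets met this criterion, all lower in transgenic muscle. By group means, 4 probe sets differed at least 2-fold, of which 2 were higher and 2 lower. The 2 arrays of one group did not overlap with those of the other for 36.7% of probe sets, 2239 higher and 1691 lower in transgenic muscle. Chance gives 33.3% for independent values. The share was 43.5% when the 4 arrays were parted by replicate number and 19.9% in the remaining split. A probe set kept apart by a given split overlaps in the others, so these shares depend on each other. They are no independent range against which to judge 36.7%. Left-out arrays changed the 2-fold count, which was 25 without transgenic replicate 2, 16 without wild-type replicate 1, 5 without wild-type replicate 2 and 1 without transgenic replicate 1.

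The probe sets carry mouse UniGene cluster numbers, which no table used here pairs with gene symbols or genome positions. They are therefore given by cluster number, without gene name, coordinates or annotation, and the groups of genes chosen for this tissue were not tested. Mm.21697_at was the only probe set picked by the preset rule, and it did not pass the threshold. Its log2 expression was 7.59 ± 0.14 (SD, n = 2) in transgenic and 8.60 ± 0.32 (SD, n = 2) in wild-type muscle, a difference of -1.01 ± 0.20 (SE) with a limma adjusted p of 0.81. The other 3 probe sets were chosen after their values were seen. Mm.406240_at, with the smallest p among lower probe sets, was at 5.67 ± 0.15 in transgenic and 6.53 ± 0.27 in wild-type muscle (SD, n = 2 each), a difference of -0.86 ± 0.14 (SE). Both its transgenic values, 5.56 and 5.78, lay below the filter value of 6.02, so it was kept only through its wild-type values. Whether its transgenic level lay above background was not known. Mm.250391_at, with the smallest p among higher probe sets, was at 7.20 ± 0.13 in transgenic and 6.53 ± 0.27 in wild-type muscle, a difference of 0.66 ± 0.15 (SE). Mm.379070_at had the widest gap in the upward direction and was at 10.33 ± 0.08 in transgenic and 9.47 ± 0.47 in wild-type muscle, a difference of 0.86 ± 0.24 (SE). The limma adjusted p of each was 0.81. With the replicate block, the limma adjusted p was 0.041 for Mm.21697_at, 0.00096 for Mm.406240_at, 0.041 for Mm.250391_at and 0.067 for Mm.379070_at. These values rest on 1 residual degree of freedom and mostly on a variance shared over probe sets. With cyclic loess added to the block, Mm.406240_at passed with an adjusted p of 0.0015, and Mm.21697_at and Mm.250391_at were both at 0.059. Without the block and without wild-type replicate 1, the log2 differences of these probe sets, in the order above, were -1.24, -1.05, 0.85 and 0.52. Without wild-type replicate 2 they were -0.78, -0.68, 0.47 and 1.19. Both fits leave 1 wild-type array, so only the differences are given.

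**Figure D1:**
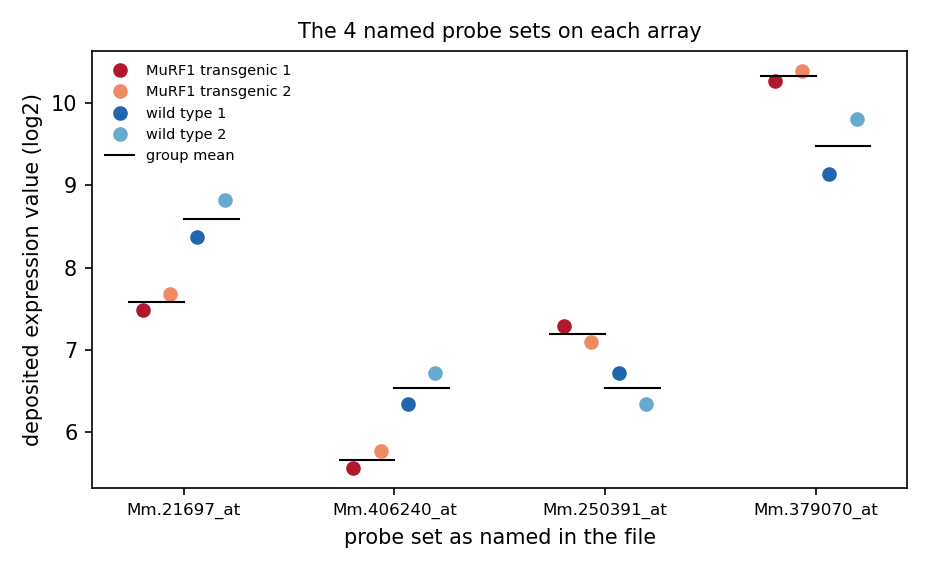
Deposited log2 expression (vertical axis) of the 4 named probe sets (horizontal axis) on each array, with a point for each array and a horizontal line for the mean of the 2 arrays of a group. Mm.21697_at and Mm.406240_at were lower, and Mm.250391_at and Mm.379070_at higher, in both transgenic arrays than in both wild-type arrays. None passed an adjusted p of 0.05 in the fit on all 4 arrays without a replicate block (limma, adjusted p 0.81 each).

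The probe set that measures Trim63, the overexpressed gene, could not be named, so the group labels were not checked against it. Over all 17867 probe sets, the widest upward gap between the lower transgenic and the higher wild-type array was 0.47 on the log2 scale, at Mm.379070_at. The widest downward gap was 0.72.

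The 95% confidence interval of the difference (limma) lay within 2-fold in either direction for 10439 probe sets, or 97.4%. This share was 99.9% in the dimmest tertile of probe sets and 93.1% in the brightest tertile, whose median standard errors were 0.08 and 0.16 on the log2 scale. The standard deviation of the differences over probe sets was 0.10 in the dimmest and 0.23 in the brightest tertile. The median difference was 0.03 in the dimmest, 0.02 in the middle and -0.01 in the brightest tertile. Known changes of 1.5-fold, 2-fold or 4-fold were added to 200 probe sets of these arrays. Of these, 80.6% of 2-fold and 46.9% of 1.5-fold changes were called, with 2 calls per run among the other probe sets. With the replicate block these shares were 97.8% and 81.3%, with 154 calls per run among the other probe sets. Many added changes ease the adjusted threshold, so the shares do not describe arrays with few changes. Without added changes, Mm.21697_at, 2.01-fold lower by group means, had a limma adjusted p of 0.81.

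Arrays of the same group were not closest to each other. Across the probe sets tested, Pearson's r was 0.971 between the 2 transgenic arrays and 0.982 between the 2 wild-type arrays. It was 0.989 between transgenic replicate 2 and wild-type replicate 1, the closest pair, and 0.949 between transgenic replicate 1 and wild-type replicate 2, the most distant. These correlations are across probe sets, which are not independent replicates. Between the distant pair 147 probe sets lay at least 2-fold apart, against 26 between the closest pair. Transgenic replicate 1 also had a narrower range of expression than the other arrays, with an interquartile range of 1.03 against 1.08 to 1.11.

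**Figure D2:**
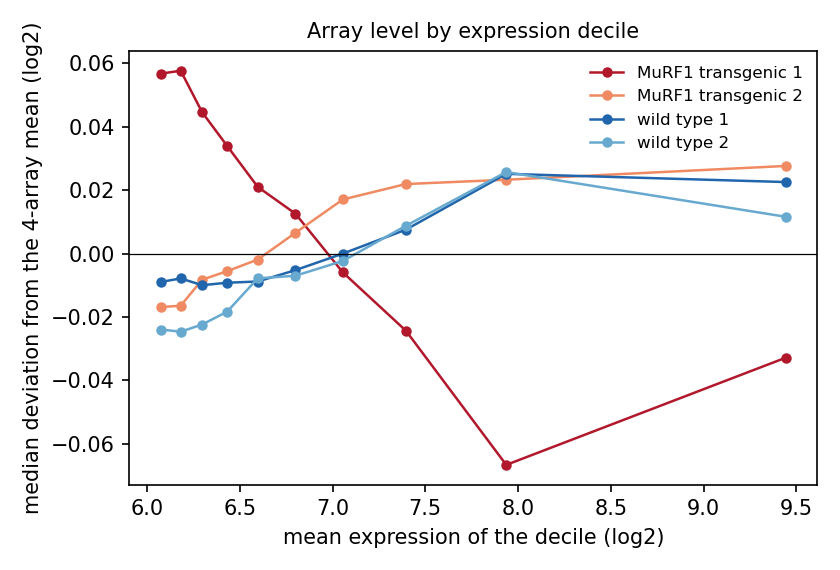
Median deviation of each array from the mean of the 4 arrays (vertical axis, log2) against mean expression (horizontal axis, log2), with a point for each decile of the 10720 probe sets by mean expression and a line for each array. Transgenic replicate 1 lay at 0.057 in the dimmest decile and at -0.067 in the decile next to the brightest, whereas the other 3 arrays stayed between -0.025 and 0.028.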

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

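The count of 0 probe sets past adjusted p 0.05 was also obtained without the intensity trend, with a robust fit, without moderated variances, under both other filters and the 3 other normalizations, with an adjusted p under 0.1, and, chosen after seeing the data, without the 500 probe sets of largest first-component loading. Array weights, also added later, gave 0 but cannot tell the 2 arrays of a group apart, so they check no single array. An unadjusted p under 0.01 (limma) was reached by 33 (27 lower), or 0.31% of those tested, which is also fewer than chance gives. The series' text does not tie its pairs to the replicate numbers. The groups' replicate differences correlated (r = 0.48, across probe sets). Transgenic array 2 and wild-type array 1 were closest (r = 0.989), which does not decide whether the numbers mark pairs. The replicate block leaves 1 residual degree of freedom, beside 9.09 prior degrees of freedom. With it, 18 probe sets passed (16 lower, 2 higher in transgenic muscle) and 1617 had an unadjusted p under 0.05 (limma). With cyclic loess added to the block after seeing the data, these counts were 1 and 1695. Without 1 array in turn, 0 to 40 passed and 134 to 2074 had an unadjusted p under 0.05, the lone array being assumed to vary like the other group. The latter count was 628 without a filter and 204 with the stricter one, as other numbers were tested. Probe sets apart in every cross comparison numbered 4 at 1.5-fold and 1 to 25 without 1 array, where fewer comparisons had to be met, and otherwise 0. The share of lower probe sets, 68.3% as reported, was 43.9% without moderated variances, 46.8% to 65.7% without 1 array, 73.2% with median centring, 74.4% with array weights and 76.5% with cyclic loess; the cause was not tested. Only another normalization could have reversed the named probe sets' signs, as their groups do not overlap, and none did. Mm.406240_at was not kept by the stricter filter, nor any but Mm.379070_at by the one on loading. Trim63, gene lists and control ratios were not run for lack of names or because names were in doubt, and pseudocounts do not apply to log2 values.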

Other observations

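The tests of explanations in this part were chosen after the results were seen; the genotype counts were planned.

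The split by replicate number separated more probe sets than genotype did. The closest arrays, transgenic replicate 2 and wild-type replicate 1 (r = 0.989), differ in number, which does not count against an effect of the number. On the first principal component, the arrays lay at -19.4 (transgenic 1), 0.38 (wild type 1), 3.95 (transgenic 2) and 15.0 (wild type 2). Replicate 2 lay higher in both groups and wild type lay higher for both numbers, which leaves the closest pair in the middle. Arrays 1 of both groups against arrays 2 of both groups gave 8 probe sets past adjusted p 0.05 (limma) and 899 at an unadjusted p under 0.05, against 0 and 315 for genotype and 0 and 84 for the third way of parting the 4 arrays. So 2 of the 3 splits, the real one included, gave at least as many probe sets as genotype, and 3 splits are too few for a share under 0.05. Shared handling of arrays with the same number stays open: 51 of the 64 control rows were higher in replicate 2 in both groups, but control rows of an array shift together (medians of 0.29 and 0.42 on the log2 scale), so this amounts to 2 signs that agree and does not decide. A smooth intensity-dependent difference left by the normalization is argued against, since the correlation between the groups' replicate differences was 0.48 before and 0.50 after cyclic loess. A litter or other biological difference shared by same-numbered mice, or the pairs that the series' text mentions, also stays open and untested.

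No probe set stood well above wild type in both transgenic arrays, although one gene was overexpressed by design. The widest upward gap, 0.47 on the log2 scale, limits how far the lower transgenic array lay above the higher wild-type array in any listed probe set, but not the change itself: by group means Mm.379070_at was 0.86 higher, with a 95% interval up to 1.44, and 2 probe sets were at least 2-fold higher. An exchange of arrays between the groups may be considered: the split by replicate number held 4 probe sets at least 2-fold apart in every cross comparison, with a widest gap of 2.22, and the third split held 1, with a widest gap of 1.03. Because both other splits held such probe sets, and the control rows also moved with the number, these counts do not decide whether arrays were exchanged. A transgene transcript without the part of Trim63 that the probes cover, or a probe set that was not analysed here, also stays open, as neither was tested.

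Control rows named for the same transcript differed in level. Of 9 pairs of control rows named for the same spike transcript and end (BioB, BioC, BioD and Cre), the members differed by a median of 1.57 and by up to 5.23 on the log2 scale, and the rows named for Cre in the newer control set lay at 5.50 and 5.30, near the lowest values of the table. When the first run of names was moved 3 rows down and the second 9 rows up, the pairs differed by a median of 0.56, and the levels rose in the order BioB, BioC, BioD and Cre from 7.22 to 12.5. Names attached to the wrong values within the control block stay open as an explanation, because the placement was found by inspection and 29 of the 1831 placements compared came as close. Whether names of the cluster probe sets are displaced was not tested, which is a limit on every cluster number given here.

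The differences of transgenic from wild-type arrays correlated across probe sets at 0.37 when same-numbered arrays were compared and at -0.18 when the numbers were crossed. Parted from the other 3 arrays, transgenic replicate 1 held 21 probe sets at least 2-fold apart from each of them, wild-type replicate 2 held 12, wild-type replicate 1 held 3 and transgenic replicate 2 held 1.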
